A study of Ambystoma mexicanum with 42 samples.

How the data were processed

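The series profiled axolotl tissues by RNA sequencing. Per the labels' protocols, RNA was extracted with Trizol or RNeasy columns, libraries were made with the TruSeq v2 chemistry, and paired-end reads of 100 bases were sequenced on an Illumina HiSeq. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic and RSEM were used; their settings and roles, and the versions of the last 2, are not given in the sources used here. The TruSeq v2 chemistry is not stated by the labels to keep strand, so reads of a gene and an overlapping antisense gene cannot be separated.

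The authors deposited a table of expected counts and a table of FPKM values for the transcripts of a de novo assembly. The expected counts, deposited by the authors, are RSEM estimates that share reads among similar transcripts, so 23.5% of the values above 0 were not whole (tolerance 1e-06). The FPKM values, per the deposited table, carry a TMM normalization made by the authors. The tables held 1554055 transcripts of 1388798 Trinity genes, a Trinity gene being a group of assembled transcripts, of which 297332 transcripts and 250603 genes had no count in any library. An assembly of this kind can split a gene into several Trinity genes or merge close copies, so a count of Trinity genes is not a count of genes, and near-identical copies share reads in an uncertain way. The row names were bare assembly names. None (0) of them matched the given gene table of the assembly UKY_AmexF1_1, so no gene symbols, coordinates or fixed lists of named genes were used. Every column of per-sample values was mapped to a library by its name.

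Expected counts were summed over the transcripts of a Trinity gene and rounded to whole numbers. The comparisons, groups, tests, gene sets, named genes rule and most alternatives were fixed before the data were examined. Libraries were grouped by the tissue in the labels. The main test was edgeR 4.0.16, in R 4.3.3, with data.table (1.17.8) for the tables: TMM scaling, filterByExpr with its minimum count of 10, a quasi-likelihood fit on group means and a quasi-likelihood F test, with Benjamini-Hochberg adjusted p below 0.05 as a change. Each comparison was fitted on a family of related tissues: the 14 limb and blastema libraries, the 9 cartilage and bone libraries, the 10 skeletal muscle, heart and blood vessel libraries, and the 7 gonad libraries. Groups of few libraries thereby share an estimate of the spread. Blastema against intact limb compared the mean of the 2 blastema groups with the mean of the 4 limb segments, and cartilage against bone used the mean of the 2 cartilage groups.

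Tissue sets were built only from libraries outside the limb family, so they are independent of the libraries compared there. Each of the 9 sets took up to 200 genes with the largest gap between the mean log2 CPM in that tissue and in the next of the 9 tissues, with a gap of at least 2 and a level of at least 3. Log2 CPM used a prior count of 2. Sets with at least 5 measured genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the sets, and again with a correlation estimated per set. For blastema against intact limb, each set's mean log2 CPM per library was also put to an exact two-sided permutation test, a step chosen after the data were seen. The genes called between hand and upper arm were used as 2 position sets in the blastemas. Tissue-enriched genes came from 1 fit of all 42 libraries in 11 tissue classes, with gill filament and embryo as comparators only.

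The rule for named genes was that, without gene symbols, only the 2 highest and the 2 lowest log2 fold changes of blastema against intact limb are named, among changed genes with a mean log2 CPM of at least 4 and no overlap between the groups (4716 genes passed). Where all libraries of a group had a count of 0, a fold was bounded by 3 counts per library, and medians of sets are also given with such genes at their bound. Replicate libraries were compared by chi-square tests of their counts. The lanes of the blastema libraries, from their titles, cross the groups: proximal 1 and distal 2 were in lane 8, and proximal 2 and distal 1 in lane 6. The difference between lanes was shared by proximal and distal libraries, with a correlation of 0.534 across 32789 genes, which are not independent replicates.

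Alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, all genes with a total of at least 10 counts, a fit of all 42 libraries, counts per transcript, and limma on log2(FPKM + 1), where a pseudocount of 1 understates the change of low genes. Others were each library left out, 50 or 500 genes per set, 2-fold or 8-fold enrichment, lane as a block, and a fit of the 4 blastema libraries. Alternatives added after the data were seen were thinning of the limb and blastema libraries to one depth, the run of library numbers as a block, 2 other choices of position genes, and testes against ovaries without the 3 most abundant testes genes. The labels mark no runs. The limb libraries were cut into 3 runs here, in the order of their library numbers, with a new run at each hand library.

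The tests were tried on simulated counts drawn from the means and depths of these libraries with 200 genes changed. For blastema against intact limb (29561 genes) edgeR recovered 35.8%, 92.5% and 89.4% of genes changed by a log2 fold change of 1, 2 and 3, with 24 false calls. These stood beside 24, 62 and 59 recovered genes. DESeq2 made 93 false calls beside 36, 66 and 64 recovered genes, and limma made 13 beside 20, 57 and 58. In each tool false calls made up a larger share of the calls than the adjusted p threshold allows. For distal against proximal blastema (29807 genes) the shares recovered by edgeR were 1.49%, 49.3% and 77.3%, and for hand against upper arm (29661 genes) 7.46%, 65.7% and 77.3%. For wrist against long-bone cartilage (25128 genes) they were 0%, 17.9% and 57.6%, for cartilage against bone (25197 genes) 0%, 46.3% and 78.8%, for muscle against heart (32442 genes) 7.46%, 50.8% and 84.8%, and for testes against ovaries (23486 genes) 4.48%, 25.4% and 68.2%. The set test called the 1 changed set of 8 and 0 others. Its sets were random genes drawn independently of each other, whereas the real skeletal muscle set had an estimated correlation of 0.553. The simulation therefore cannot show how often the preset correlation gives false calls for the real sets. The enrichment step recovered 74.5% of 200 genes raised 8-fold in blastema (48351 genes), with 0 false calls. All other simulated genes had the same mean in every tissue and a capped spread, so false calls could hardly arise. Their number says nothing about false calls in libraries of differing tissues.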

Results

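RNA was sequenced from 42 libraries of the axolotl, a salamander that regrows amputated limbs, and the libraries came from 16 tissue groups. The intact limb was sampled as upper arm (3 libraries), elbow (2), forearm (2) and hand (3). The regenerating limb was sampled as blastema, the mass of progenitor cells that forms at an amputation stump, after a proximal amputation (2) or a distal one (2). The other groups were wrist cartilage (3), long-bone cartilage (3), bone (3), skeletal muscle (4), heart (3), blood vessel (3), testes (4), ovaries (3), gill filament (1) and whole early embryo (1). The stated purpose was to find transcripts needed for regeneration and to provide a map of expression over tissues. All animals were wild-type and of the leucistic, pale-skinned strain. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Gill filament and embryo had no replicate.

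The estimated counts per library (in mega-counts, M) summed to 9.24 to 34.8 M in the intact limb and to 41.4 to 65.2 M in blastema. The totals were 9.09 to 45.2 M in cartilage, 9.24 to 14.4 M in bone, 15.8 to 30.7 M in skeletal muscle and 14.8 to 25.7 M in heart. Blood vessel libraries held 21.5 to 38.7 M counts, testes 9.23 to 28.0 M, ovaries 10.4 to 12.8 M, gill filament 15.7 M and the embryo 97765013. A few genes took a large share of some libraries. In the embryo 1 Trinity gene held 40.4% of the counts and another held 22.5%. A group of 3 Trinity genes held 1.56%, 28.3%, 9.49% and 62.0% of the counts of testes 1 to 4, and the same 3 genes held 9.74% of upper arm 1 and 6.89% of ovaries 3. Within each group the replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 17.9 in each of the 40 pairs, which separate preparations of one sample would also show.

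Libraries of one tissue resembled each other far more than libraries of different tissues. The median Spearman correlation across genes was 0.952 within groups (40 pairs) and 0.687 between groups (821 pairs), over 27071 genes. The intact limb segments were nearly alike, with a median correlation of 0.964 over 45 pairs and a range of 0.924 to 0.987. Blastema was closer to bone (median 0.787) and cartilage (0.785) than to intact limb (0.751) or skeletal muscle (0.673), except for distal blastema 1, which was closer to intact limb (median 0.803) than to bone (0.747) or cartilage (0.729). Gill filament was closest to intact limb (0.819), the embryo was closest to ovaries (0.788), and testes stood apart from every other tissue, with medians of 0.286 to 0.535. Of the 40 libraries with a replicate, 24 were nearest to a library of their own group. The others were libraries of limb segments, distal blastema and cartilage, each nearest to a sister group. Skeletal muscle 4 correlated with the other muscle libraries at a median of 0.898, while the other 3 muscle libraries had medians of at least 0.971, and wrist cartilage 2 reached 0.861 with a muscle library. This description has no test, and genes are not independent replicates.

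**Figure D1:**
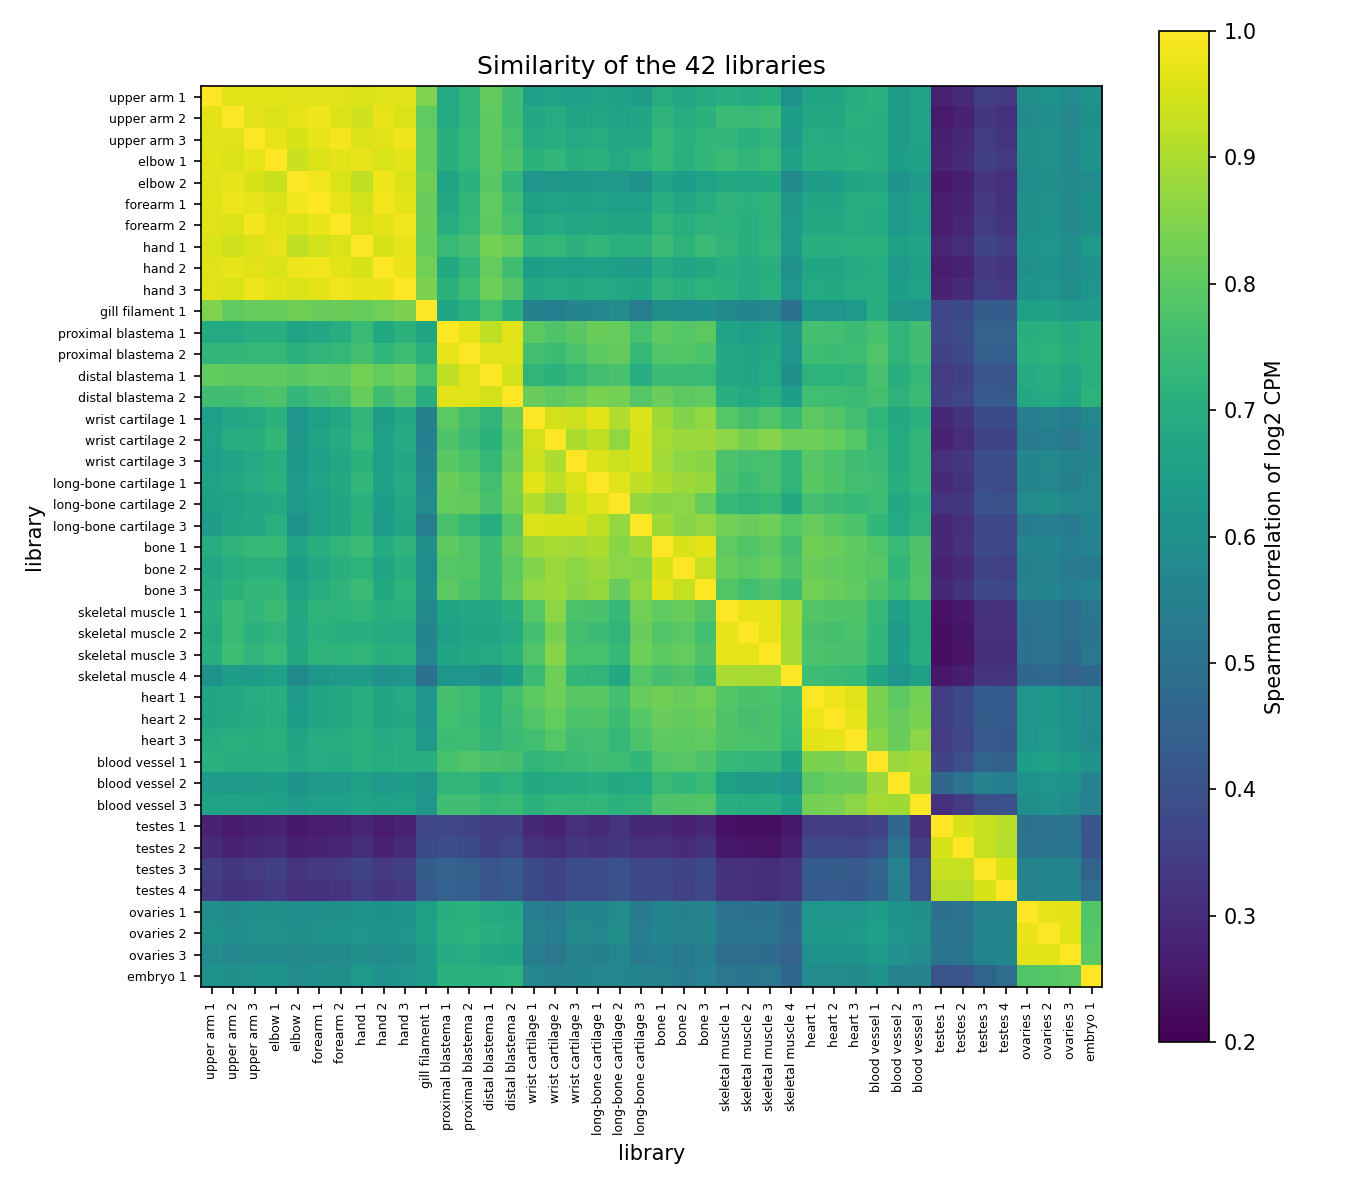
Spearman correlation of log2 CPM, by color, between each pair of the 42 libraries, which are named on both axes and ordered by tissue. Blocks of high correlation lie along the diagonal for each tissue, intact limb libraries correlate at 0.924 to 0.987, and the 4 testes libraries are dark against every other tissue.

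In the main fit, blastema and intact limb differed in most of the genes tested. Of 32789 Trinity genes, 11926 were higher in blastema (4 libraries) and 11636 were lower than in intact limb (10 libraries), which together make 71.9%, and the change was at least 4-fold for 4087 of the higher and 6019 of the lower genes. Among genes of fair abundance, c1087001_g2 rose by a log2 fold change of 11.76 (SE 0.48; edgeR adjusted p = 9.96e-09), from 0.0415 ± 0.0614 CPM in limb (SD, n = 10) to 60.3 ± 22.2 CPM in blastema (SD, n = 4). The gene c1076561_g4 rose by 10.72 (SE 0.43; edgeR adjusted p = 1.84e-09), from 0.319 ± 0.219 to 472 ± 167 CPM. The gene c1062142_g1 fell by 15.73 on the log2 scale (SE 1.20; edgeR adjusted p = 1.45e-06), from 3059 ± 2192 CPM in limb to 0.235 ± 0.470 CPM in blastema, where distal blastema 2 alone held counts (70). With 3 of 4 libraries at 0 this fitted value depends on the prior count, and it was -18.90 without distal blastema 2. The gene c1080627_g2 had no count in any of the 4 blastema libraries and a median of 111 CPM in limb (range 10.8 to 3066, the highest in elbow 2).

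A count of 0 allows up to 0.0620 CPM in the shallowest blastema library, from a floor of 3 counts per library, so c1080627_g2 was at least 1794-fold lower in blastema than the limb median. Its fitted log2 fold change of -15.41 (SE 1.41; edgeR adjusted p = 8.98e-06) depends on the prior count and is no bound, and c1087001_g2 had 6 counts in total over the 10 limb libraries. Such floors and intervals cover counting error only. In the other tissues, scaled over all 42 libraries, c1062142_g1 was highest in skeletal muscle (19750 CPM), with 2090 CPM in bone and 498 CPM in cartilage. The gene c1080627_g2 reached 482 CPM in blood vessel and 121 CPM in skeletal muscle. The gene c1076561_g4 was next highest in cartilage (28.6 CPM), and c1087001_g2 was next highest in ovaries (14 CPM) and embryo (6.29 CPM). The row names carry no gene symbols, so what these genes encode is left open.

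In the edgeR fit the groups did not overlap for 48.4% of the genes, against 0.2% by chance. Blastema libraries carry lane labels and limb libraries carry library numbers instead, so batch and group cannot be told apart in this comparison, and blastema libraries were also deeper. With a filter on a total of at least 10 counts, a minority of genes changed (43000 of 87990), 29781 higher and 13219 lower.

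Genes that marked skeletal muscle or gill filament among the 9 tissues outside the limb family were almost all lower in blastema. Limb was not among the tissues compared, so these genes may be as high in limb as in their own tissue. Of 140 measured genes of the skeletal muscle set, 131 fell and 3 rose, with a median log2 fold change of -5.24 (-4.95 with genes at a count of 0 placed at their bound). Of 166 gill filament genes, 146 fell and 1 rose (median -5.72, or -5.61 at the bound). Cartilage genes went the other way, with 117 of 185 higher and 34 lower (median 1.60), and of 49 embryo genes 31 rose and 13 fell (median 3.16). Only 49 of 200 genes of the embryo set were measured. The filter kept genes with enough counts in limb or blastema, so for a set low in limb, such as embryo, the direction was partly built in. Tests of the embryo set carry the same limit. Heart genes were lower by a smaller amount, with 54 of 112 lower and 31 higher (median -0.85).

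The preset-correlation camera test called these 5 of 8 sets, with adjusted p = 1.12e-24 for skeletal muscle, 2.91e-26 for gill filament, 5.03e-05 for cartilage, 0.0162 for embryo and 0.0262 for heart. None of the 5 calls held with an estimated correlation, where adjusted p = 0.282, 0.0991, 0.690, 0.242 and 0.690 in the same order. An exact two-sided permutation test over the 1001 splits of the 14 libraries, on each set's mean log2 CPM per library, gave p = 0.000999 (adjusted p = 0.002), the smallest it can give, for skeletal muscle (2.13 ± 0.611 in limb, n = 10; -2.02 ± 0.589 in blastema, n = 4). The same exact p was found for gill filament (3.76 ± 0.337 against -1.02 ± 1.27), heart (1.31 ± 0.263 against 0.457 ± 0.230) and embryo (-1.05 ± 0.237 against 0.0481 ± 0.210). For cartilage the exact test gave adjusted p = 0.0288, with 1.78 ± 0.503 in limb and 2.74 ± 0.848 in blastema. The exact test takes the libraries as independent of each other. Deviations of the limb libraries from their segment means correlated at 0.451 within runs of library numbers and at -0.217 between runs. The exact p-values may therefore be too small. Bone genes (median 0.30, 53 of 145 higher and 36 lower), blood vessel genes (median 1.57, 20 of 34 higher and 6 lower) and ovary genes (median 0.12, 34 of 90 higher and 28 lower) passed neither test (camera adjusted p = 0.324, 0.277 and 0.663; exact permutation adjusted p = 0.876, 0.436 and 0.0519). For bone the mean level differed by -0.04, opposite in sign to the median of its genes. Only 3 of 200 testes genes were measured, and that set was not tested.

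The gill filament and embryo sets rest on 1 library each, and the gill filament library number directly precedes those of the limb libraries, while blastema libraries carry none. Without distal blastema 2 the cartilage median was 0.82, and the heart call was lost without hand 1 (-0.69, camera adjusted p = 0.0950) or proximal blastema 2 (-0.87, camera adjusted p = 0.0564). With 50 genes per set the embryo median turned to -3.73 and the cartilage, heart and embryo calls were lost (camera adjusted p = 0.270, 0.161 and 0.145), while with 500 genes the embryo median was 1.41.

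**Figure D2:**
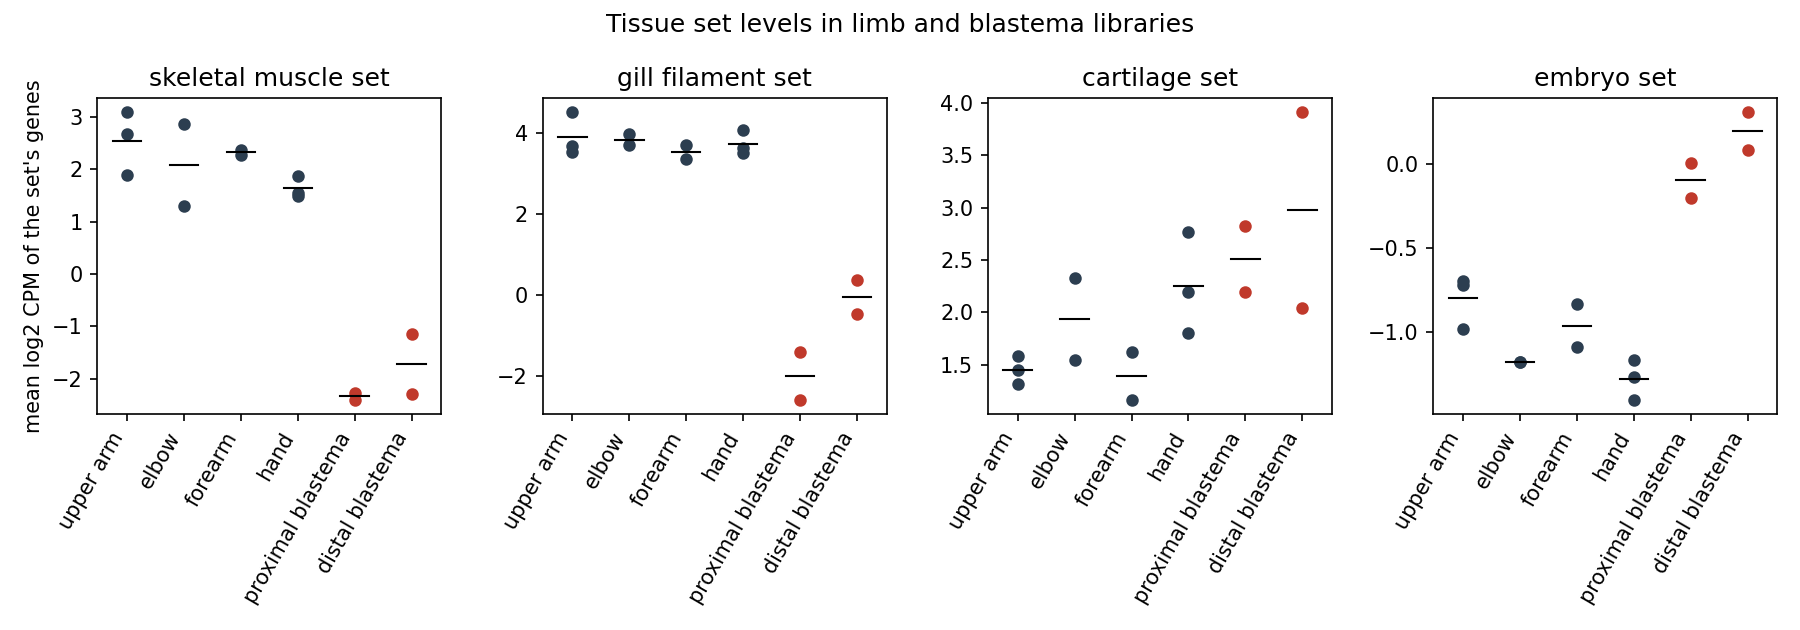
Mean log2 CPM of the genes of 4 tissue sets (vertical axis) in each limb and blastema library (points; blastema in red, intact limb in dark blue), with the group mean as a bar. All 10 limb libraries lie above all 4 blastema libraries for the skeletal muscle and gill filament sets, and all 4 blastema libraries lie above all limb libraries for the embryo set.

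The changed genes were also divided by the tissue outside the limb in which each was most abundant. Of 5013 measured genes that were highest in gill filament, 71.9% fell in blastema and 9.54% rose. Of 4681 genes highest in skeletal muscle, 48.5% fell and 24.6% rose. By contrast 57.7% of 5572 genes highest in embryo, 56.4% of 2914 highest in cartilage and 48.8% of 2476 highest in bone rose. Of genes highest in heart 26.7% rose and 41.2% fell, and of those highest in ovaries 39.6% rose and 24.5% fell. Genes highest in testes (35.1% higher, 32.6% lower) and in blood vessel (30.5% higher, 36.2% lower) were spread more evenly. The blood vessel shares leaned opposite to the blood vessel set, and the bone shares (48.8% higher, 21.2% lower) went beyond the bone set, neither of which was called. These shares are counts of edgeR calls and were not tested against each other.

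Distal blastema exceeded proximal blastema in 550 genes and was lower in 36, of 32789 tested in the fit of all 14 limb and blastema libraries (2 against 2 libraries). The change was at least 4-fold in 442 of the higher and 29 of the lower genes. The groups did not overlap for 29.2% of genes, which is below the 33.3% that chance gives for 2 against 2 libraries. Of the 550 genes higher in distal blastema, 509 were lower in blastema than in intact limb and 19 were higher, where independent lists would share 195 and 200. Both comparisons used the same 4 blastema libraries.

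The size of this list rested on the libraries and the model. A fit on the 4 blastema libraries alone, with 2 residual degrees of freedom, called 0 genes in edgeR. In that edgeR fit 2623 of 43113 genes had an unadjusted p below 0.05. The other tools were run on the limb and blastema libraries together. There DESeq2 called 1610 genes, limma called 119, and edgeR with lane as a block called 1592. Leaving out proximal blastema 1 left 58 genes, and leaving out distal blastema 2 gave 1532. The count also fell without hand 3 (260), upper arm 3 (273), upper arm 1 (283), forearm 2 (335), forearm 1 (337) or upper arm 2 (380). Transcript-level counts gave 278 genes and thinning to a common depth 334. Leaving out 1 blastema library also sets the lanes out of balance between the groups, so such counts cannot tell a single library from its lane.

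Gill filament genes were the clearest group that was higher in distal blastema. Their median log2 fold change was 2.61 (2.19 at the bound), and 30 of 166 genes rose individually while 0 fell (edgeR; camera adjusted p = 7.19e-43, and adjusted p = 0.0415 with an estimated correlation). The mean level of the set was -0.05 ± 0.607 log2 CPM in distal and -1.99 ± 0.823 in proximal blastema (SD, n = 2 each). Within lanes the distal library exceeded the proximal one by 2.10 and by 1.8. Without distal blastema 1 the median was 1.41 and was still called. Muscle genes had a median of 1.31 (0.71 at the bound; 1 of 140 rose; camera adjusted p = 1.02e-05, and adjusted p = 0.793 with an estimated correlation), and this came from 1 library, since without distal blastema 2 the median was -0.01 and the call was lost (adjusted p = 0.162).

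Blood vessel genes had a median of -0.82 in distal against proximal blastema, with 0 of 34 genes changed individually (edgeR; camera adjusted p = 2.72e-05, and adjusted p = 0.469 with an estimated correlation). Without proximal blastema 2 it was -0.03 (adjusted p = 0.127) and without distal blastema 2 -0.41. Cartilage genes had a median of 0.48 that was not called (camera adjusted p = 0.0732). It passed the test at 0.89 without distal blastema 1, at 0.94 without proximal blastema 1 and at 0.41 to 0.48 without elbow 1, hand 3, upper arm 1 or upper arm 3, and without distal blastema 2 it passed in the opposite direction, at -0.52 (camera adjusted p = 7.67e-06). Bone (median 0.00), heart (0.38), ovary (-0.09) and embryo (-0.10) genes were not called (camera adjusted p = 0.194, 0.184, 0.219 and 0.811), although heart genes were called at 0.48 without distal blastema 1 and bone genes at -0.06 without proximal blastema 1. Embryo genes turned to 4.05 with 50 genes per set and were called there and, at -0.11, with 500. Ovary genes were called at -0.08 with 500 genes per set. Cartilage genes were also called with 50 genes per set (1.45), with DESeq2 size factors (0.45) and after thinning to one depth (0.56).

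Hand and upper arm, the ends of the intact limb, differed in few genes. Of 32789 genes, 40 were higher in hand and 13 were higher in upper arm (3 against 3 libraries; edgeR), with a change of at least 4-fold in 37 and 12 of them. Muscle genes were lower in hand, with a median log2 fold change of -0.93 over 140 genes (camera adjusted p = 2.06e-31, and adjusted p = 0.217 with an estimated correlation), and cartilage genes were higher, with a median of 0.55 over 185 genes (adjusted p = 4.82e-17, and 0.268 with an estimated correlation). Embryo genes (median -0.94, 49 genes, adjusted p = 2.08e-05) and bone genes (median -0.25, 145 genes, adjusted p = 9.10e-08, and 0.217 with an estimated correlation) were lower in hand. Only 3 muscle genes, 2 cartilage genes and 1 bone gene passed the test individually.

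With an estimated correlation the embryo call held (adjusted p = 0.0123) and the muscle, cartilage and bone calls were lost. Between hand and upper arm libraries of the same run of library numbers, the mean set level differed by 0.62, 0.36 and 1.45 log2 CPM for cartilage, -0.29, -0.47 and -0.68 for embryo, -1.17, -1.53 and -0.03 for muscle and -0.49, -0.87 and 0.03 for bone. With 500 genes per set the embryo call was lost (median -0.02, adjusted p = 0.444). The bone median was -0.39 without hand 1 and -0.12 without upper arm 3, and the cartilage median was 0.31 without hand 1. Gill filament (median -0.10), blood vessel (-0.28), ovary (-0.09) and heart genes (0.07, with a test that pointed down) were not called (camera adjusted p = 0.358, 0.5259, 0.611 and 0.991). Blood vessel genes were called at -0.63 without upper arm 2, heart genes at -0.15 without hand 1, and gill filament genes without hand 3 (-0.15), upper arm 2 (-0.18) or upper arm 3 (median 0.01). The groups did not overlap for 10.1% of genes, where chance gives 10% for 3 against 3 unpaired libraries. The count of changed genes was 62 with the run of library numbers as a block and 235 in DESeq2 (116 higher, 119 lower), 98 in limma and 25 over transcripts. It was 92 without distal blastema 1, 93 without distal blastema 2, 31 without upper arm 1, 26 without hand 3, 18 without upper arm 2 and 16 without upper arm 3.

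Genes that marked the hand were also higher in distal than in proximal blastema. The 40 hand genes had a median log2 fold change of 1.47 (0.77 with genes at a count of 0 at their bound), 35 of 40 were positive and 3 rose individually (camera adjusted p = 1.00e-07, and adjusted p = 0.00102 with an estimated correlation). The 13 upper-arm genes had a median of 0.08 with 7 of 13 positive, while the camera test pointed to lower values in distal blastema and missed the threshold (adjusted p = 0.0536, and adjusted p = 0.269 with an estimated correlation). That test passed with lane as a block (adjusted p = 0.0462). With the genes chosen anew each time, it also passed without distal blastema 1 (median 0.78), distal blastema 2 (-0.46), proximal blastema 1 (0.05), hand 1 (-0.25), hand 2 (-0.43), elbow 1 (0.04), elbow 2 (0.04), forearm 1 (0.00) or forearm 2 (0.00), and the median was 1.37 without proximal blastema 2. Of the 40 hand genes 22 were lower in blastema than in intact limb and 6 were higher, and of the 13 upper-arm genes 11 were lower and 1 was higher.

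Wrist cartilage and long-bone cartilage were not told apart. No gene of 26227 changed in edgeR (3 against 3 libraries), with 200 genes (0.763%) at an unadjusted p below 0.05, and DESeq2 and limma also called 0. The groups did not overlap for 2.84% of genes, against 10% by chance. In simulated data of this design edgeR recovered 57.6% of genes changed by a log2 fold change of 3, 17.9% at 2 and 0% at 1, so a difference of 2-fold would not have been detectable at this depth and spread.

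Cartilage and bone differed in 3961 of 26227 genes (6 against 3 libraries; edgeR). Of these 1560 were higher in cartilage and 2401 were higher in bone, with a change of at least 4-fold in 1087 and 1438. The groups did not overlap for 19.3% of genes, against 2.38% by chance. Muscle genes varied widely among the cartilage libraries, with a mean set level of 2.63 ± 1.37 log2 CPM (SD, n = 6) against 2.97 ± 0.128 in bone (n = 3), and were not called between the tissues (camera adjusted p = 0.931, with a set made from libraries outside cartilage and bone). Without bone 3 the count was 2494.

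Skeletal muscle and heart, the striated muscles of body and circulation, differed in 14900 of 34367 genes (4 against 3 libraries; edgeR). Of these 7666 were higher in skeletal muscle and 7234 were higher in heart, with a change of at least 4-fold in 4604 and 3839. The groups did not overlap for 50.9% of genes, against 5.71% by chance. Skeletal muscle 4 held few genes at low counts, with 34929 genes at a count of at least 1 against 104224 to 129643 in the other muscle libraries, although its total of 30.7 M was the highest of the 4. Without it 16384 genes changed.

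Testes and ovaries differed in 18646 of 25221 genes (4 against 3 libraries; edgeR), with 10263 higher in testes and 8383 higher in ovaries. The change was at least 4-fold in 8470 and 5063. The groups did not overlap for 74.3% of genes, against 5.71% by chance. The median log2 fold change of all genes was 0.30, and 0.40 with DESeq2 size factors, so the choice of scaling shifted every fold change of this comparison. Leaving out the 3 genes that dominated the testes libraries gave 19753 changed genes. With all genes of at least 10 counts 36292 changed (24017 higher, 12275 lower), and DESeq2 called 33309 (23063 higher, 10246 lower).

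Tissue-enriched genes, which were tested higher in a tissue class than in the mean of the others and stood at least 4-fold over the next class, numbered 9132 in testes, 3578 in skeletal muscle and 2553 in blood vessel. There were 1344 in ovaries, 1029 in cartilage, 555 in bone, 525 in heart, 490 in intact limb and 347 in blastema, of 70559 genes tested in edgeR. These genes held 75.2% of all counts in testes, 40.7% in blood vessel and 36.3% in skeletal muscle, but 6.87% in intact limb and 1.29% in blastema. The next class was most often embryo for ovary genes (672 of 1344), heart for blood vessel genes (1664 of 2553), gill filament for limb genes (164 of 490) and cartilage for blastema genes (118 of 347).

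Of the 430 limb-enriched genes measured in the limb and blastema fit, 427 were lower in blastema, and of the blastema-enriched genes measured there 244 were higher and 0 were lower. Both lists were chosen on these same libraries, so their directions are not independent evidence. The limb-enriched genes had a median log2 fold change of 1.89 between distal and proximal blastema, with 49 higher and 0 lower in distal blastema. The blastema-enriched genes had a median of -0.22, with 2 higher and 4 lower. Without skeletal muscle 4 the count for skeletal muscle was 1561.

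**Figure D3:**
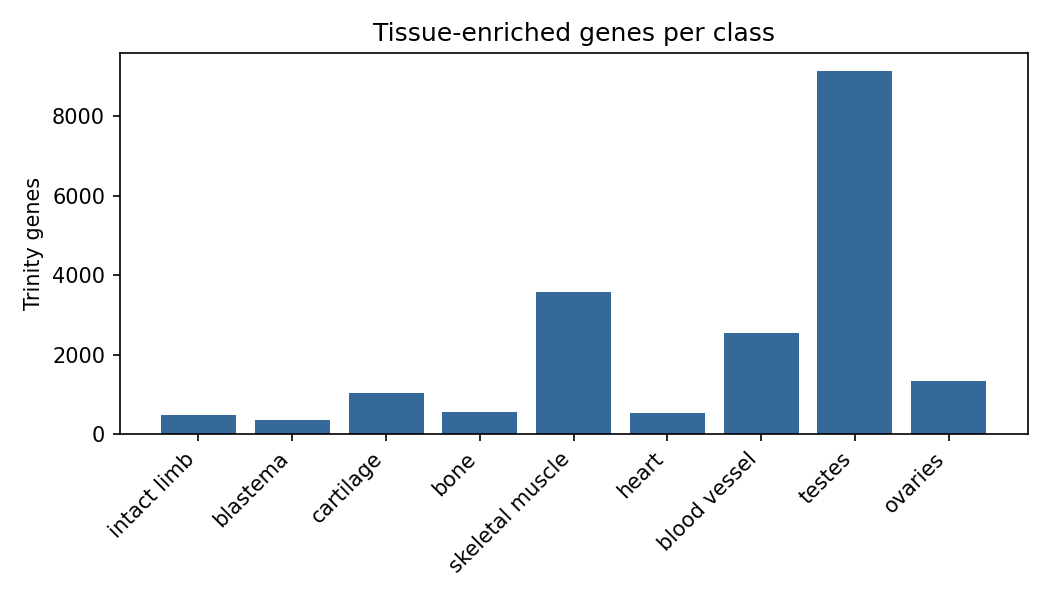
Number of tissue-enriched Trinity genes (vertical axis, bars from 0) in each of the 9 tissue classes with replicates. The counts run from 347 in blastema to 9132 in testes.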

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

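Tests of lane, of runs of library numbers, of other splits and of the hand genes at their bound were chosen only after the result was seen, as was the test of whether effects differ between blastema and intact limb.

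Single libraries lay far from the others of their class in 7 of 43 groups of values tested, where chance gives about 1 in 20 groups. In intact limb, hand 3 held 34.78 M counts against 9.24 to 15.71 in the other 9 libraries, the 3 genes abundant in testes took 9.74% of upper arm 1 (0.388 to 3.12% in the others), and c1080627_g2 reached 3066 CPM in elbow 2 (10.8 to 391 in the others). In blastema, distal blastema 2 had a skeletal muscle set level of -1.143 log2 CPM (-2.395 to -2.26 in the other 3) and held the only counts of c1062142_g1 (0.9402 CPM). Long-bone cartilage 1 held 45.2 M counts (9.09 to 17.38 in the other 5 cartilage libraries). In skeletal muscle 2 the 3 testes genes took 0.481% (0.268 to 0.284% in the other 3).

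In a fit without lane or run of library numbers as a block, the log2 step from proximal to distal differed between blastema and intact limb. This test, distal minus proximal blastema against hand minus upper arm, found 73 of 32789 genes (69 with a higher value in blastema, 4 with a lower one; edgeR). For the tissue sets the median difference was 2.803 for gill filament, 2.355 for skeletal muscle, 1.423 for embryo, -0.9777 for blood vessel and 0.1195 for cartilage (camera adjusted p = 5.85e-40, 3.30e-19, 0.000799, 0.000586 and 0.00257), and for cartilage the test pointed down against the sign of the median. With an estimated correlation gill filament and embryo passed (adjusted p = 0.0260 for both), and skeletal muscle, blood vessel and cartilage did not (adjusted p = 0.348, 0.348 and 0.720). The muscle rise between the blastemas came from distal blastema 2, without which its median was -0.01. The blood vessel median between the blastemas was -0.82, and -0.03 without proximal blastema 2, where the call was lost (adjusted p = 0.127), and the cartilage median turned from 0.48 to -0.52 without distal blastema 2. The difference was not tested with blocks, and lane as a block moved the count of genes between the blastemas from 586 to 1592. It was tested on the log2 scale only. Gill filament genes gained a median of 1.72% of their limb level in lane 8 and 5.28% in lane 6. Such a gain is a large log2 step from the low level in blastema and a small one in limb. The gill filament difference therefore need not mean a different gain in CPM.

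Genes higher in distal than in proximal blastema were mostly lower in blastema than in intact limb. The tables argue against sequencing lane as the cause, since the gill filament set was higher in the distal library by 1.8 and 2.10 within the 2 lanes. A rise of the hand genes only as part of this general rise stays open: their median of 1.47 lay at the 99.1th percentile of 10000 lists matched on the change between blastema and limb, but with genes at a count of 0 at their bound it was 0.77, at the 74.7th percentile of the same lists. A small amount of intact limb tissue of every kind in the distal libraries may explain the rise and stays open: in lane 8 gill filament genes gained 1.72% of their limb level and skeletal muscle genes 2.37%, a ratio of 0.726. In lane 6 gill filament genes gained 5.28% and skeletal muscle genes a median of 0 (quartiles -0.448 to 0.57%), so no ratio exists there, and limb tissue without muscle remains possible as does a difference between amputation levels, which was not tested separately.

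Skeletal muscle 4 held few genes at low counts. The tables argue against a minimum below which low values were removed, since 12% of its genes expected at 50 to 100 counts had 0 counts, against at most 0.0967% in the other muscle libraries. Few distinct RNA molecules, each read many times, is a candidate explanation: 3 ranges of expected count implied 24.9, 28.8 and 34.1 counts per molecule, a ratio of 1.37. The design names no biological difference for this library, so none was tested.

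Intact limb libraries were most alike within runs of consecutive library numbers. The mean correlation of their deviations from the segment means was 0.451 within runs and -0.217 between runs, and 1 of 144 reassignments of runs within segments, the real one, gave a difference as large. The tables argue against sequencing depth, since the difference was 0.617 after thinning to one depth and 0.668 before. A factor shared within a run, such as an animal or a day of preparation, is consistent with this and cannot be named from the labels. Its biological and technical forms were not tested apart.

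With libraries taken as independent, chance can be excluded for the count of changed genes by other splits of the libraries in the following comparisons. In blastema against intact limb 1 of 100 splits was as large, the real one (23562 genes against at most 14830). It was 1 of 84 in cartilage against bone (3961 against 603). Skeletal muscle against heart (14900 against 3128) and testes against ovaries (18646 against 2662) each had 1 of 35, the smallest share possible there. For them the exclusion holds only without adjustment over comparisons. These shares were not adjusted over comparisons. For blastema 100 of 1001 splits were drawn. The highest other split joined hand 3 with upper arm 2, forearm 1 and elbow 2, which are of 1 run of library numbers, so its count carries that structure. For the enriched genes 25 shuffles of all libraries were used, the real one included. Only the real one reached the count for intact limb (490 against 22), cartilage (1029 against 705) and testes (9132 against 2278). Its share, 1 of 25, is the smallest possible there and was not adjusted over the classes. Chance is therefore not excluded for any single class. For skeletal muscle (1 of 25, 3578 against 3317) the margin was narrow. Without skeletal muscle 4 the count was 1561, and no shuffles were run without that library. Shuffles gave as many genes for blastema (3 of 25 splits; 347 against 1067), bone (8; 555 against 3917), heart (11; 525 against 3862), blood vessel (3; 2553 against 3532) and ovaries (6; 1344 against 3718). Shuffles of all libraries place libraries of other tissues together, so their counts carry tissue differences, a structure of the samples. They leave chance open for these 5 classes as well. Chance cannot be excluded for the number of tissue sets called by camera in blastema against intact limb (42 of 100 splits; 5 sets against 7). The splits are too few for hand against upper arm (1 of 10 splits; 53 genes against 0) and its tissue sets (6 of 10 splits; 4 against 6). For wrist against long-bone cartilage the real count was 0 in edgeR (200 at an unadjusted p below 0.05, and 0 in DESeq2 and limma), so each of the 10 splits was as large by construction and nothing can be read from their number. The highest other split gave 1141 genes. It set wrist cartilage 1 and 2 and long-bone cartilage 3 against the rest and points to a structure of the samples other than their site.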

How the results depend on the processing

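Thinning to one depth, the block of library-number runs, the 2 other choices of position genes and the omission of the 3 testes genes were tests chosen only after the result was seen. The labels carry no replicate numbers; pairs were formed only by lane (1592 genes between the blastemas) and by run of library numbers (62 genes between hand and upper arm), each as a block. Of 149 alternatives for single sets and genes that kept all libraries, 122 kept direction and side of the threshold, 13 lost the call, 8 gained one and 6 turned direction. The 4 named genes kept their calls in the 5 other settings run for them, and their direction without each library in turn. Thinning, the run block and counts per transcript were not run for these genes. A left-out library that leaves 1 in its group assumes that this library varies like the others. A left-out blastema library also sets the lanes out of balance between proximal and distal blastema. Thinning to one depth lowered the count of changed genes in blastema against intact limb from 23562 to 20094. Simulated changes of a log2 fold change of 1 were recovered by edgeR in 0% to 35.8% of cases over the 7 comparisons. Where no construction shows the cause below, the cause was not tested.

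For all genes with a total of at least 10 counts, blastema against intact limb gave 43000 changed genes and testes against ovaries 36292, with more genes tested. The enriched genes were then 1590 in blastema, 4275 in blood vessel, 892 in bone, 1812 in cartilage, 1104 in heart, 778 in intact limb, 6170 in skeletal muscle and 14217 in testes. DESeq2 called 1610 genes in distal against proximal blastema, 235 in hand against upper arm and 33309 in testes against ovaries. In simulated counts of blastema against intact limb DESeq2 made 93 false calls, against 24 in edgeR. With DESeq2 size factors the bone set median in distal against proximal blastema was -0.01408. The fit of all 42 libraries gave 30934 genes for testes against ovaries. Limma on log2(FPKM + 1) called 119 genes between the blastemas and 98 between hand and upper arm.

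Counts per transcript gave 278 and 25 in these 2 comparisons, and enriched transcripts numbered 777 in blastema, 857 in bone, 934 in heart, 1012 in intact limb, 2791 in ovaries and 15645 in testes. A 2-fold step over the next class gave 940 genes in blastema, 1235 in bone, 1749 in cartilage, 944 in heart, 1051 in intact limb, 3129 in ovaries and 6434 in skeletal muscle. An 8-fold step gave 151 in blastema, 264 in bone, 333 in heart, 271 in intact limb, 573 in ovaries and 1931 in skeletal muscle.

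Between the blastemas, the fit on the 4 blastema libraries called 0 genes (edgeR; 2623 at an unadjusted p below 0.05; 1610 in DESeq2 and 119 in limma with the larger fit), thinning to one depth gave 334, and sequencing lane as a block 1592. Thinning gave the ovaries set a median of 0.03996. The number of position sets called was 2 with lane as a block, 2 with genes from the run-blocked fit and 2 with genes outside the gill filament, skeletal muscle and cartilage sets. With 50 genes per set, blastema against intact limb called 2 sets, the medians of bone and embryo were -0.4974 and -3.734, and the embryo set was at 4.049 between the blastemas. With 500 genes per set 5 sets were called between the blastemas, and the ovaries median in hand against upper arm was 0.03162. With an estimated correlation the number of sets called was 0 in blastema against intact limb (5 with the preset correlation), 1 between the blastemas and 1 in hand against upper arm. Over genes with a mean CPM of at least 10, the median correlation within groups exceeded that between groups by 0.4021 (0.265 over all genes used).

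Leaving out each library in turn gave 58 to 1532 genes between the blastemas, 16 to 93 between hand and upper arm, 2494 (without bone 3) to 5010 between cartilage and bone, and 1561 (without skeletal muscle 4) to 3798 enriched in skeletal muscle. The number of sets called between the blastemas was 2 to 5, and of position sets 1 to 2. Medians between the blastemas were -0.19 to 0.14 for bone, -0.52 to 0.94 for cartilage, -0.15 to 0.21 for ovaries, -0.0125 to 1.55 for skeletal muscle, -0.99 to -0.03 for blood vessel, 0.00 to 0.48 for heart and -0.46 to 1.37 for upper-arm genes. In hand against upper arm they were -0.30 to 0.12 for gill filament, -0.15 to 0.21 for heart, -0.12 to 0.0660 for ovaries and -0.63 to -0.03 for blood vessel. In blastema against intact limb they were -0.0258 to 0.36 for ovaries and -0.91 to -0.69 for heart.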

Other observations

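The sets tested in cartilage, muscle and gonads below were chosen only after the result was seen, and each was made from libraries outside the tissues compared.

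Genes typical of blastema were higher in cartilage than in bone. Of 179 measured genes of the blastema set 56 rose and 12 fell, with a median log2 fold change of 0.74 (camera adjusted p = 1.08e-05, and adjusted p = 0.786 with an estimated correlation), and the mean level was 4.19 ± 0.403 log2 CPM in cartilage (SD, n = 6) and 3.44 ± 0.207 in bone (n = 3). Blood vessel genes were lower in cartilage, with 18 of 54 lower and 7 higher (median -0.77; camera adjusted p = 1.32e-04, and adjusted p = 0.786 with an estimated correlation). No set of 8 was called between skeletal muscle and heart, where intact limb genes had a median of 1.53 and ovary genes one of -0.51 (camera adjusted p = 0.123 for both; 0.0278 and 0.0307 unadjusted).

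Genes of the gill filament set, chosen without regard to their level in the gonads, were much higher in testes than in ovaries. Of 93 measured genes 83 rose and 4 fell (median 6.21; camera adjusted p = 4.08e-15, and adjusted p = 0.1995 with an estimated correlation), and the mean level was 4.75 ± 0.482 log2 CPM in testes (SD, n = 4) and -0.36 ± 0.0351 in ovaries (n = 3). Embryo genes were lower in testes, with 45 of 63 lower and 10 higher (median -3.69; camera adjusted p = 5.75e-12, and adjusted p = 0.1995 with an estimated correlation). Muscle genes (26 of 36 higher, 2 lower, median 6.27) and cartilage genes (35 of 52 higher, 6 lower, median 2.49) were also higher in testes (camera adjusted p = 2.74e-05 and 0.0144, and adjusted p = 0.115 and 0.1995 with an estimated correlation). Intact limb, bone, heart and blood vessel genes had medians of 0.86, 1.34, 0.97 and 2.25, blastema genes had one of -0.55, and none of these sets was called. The filter kept genes with enough counts in either gonad, so for sets low in 1 gonad the direction was partly built in.

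The lowest total was 9088945 counts in long-bone cartilage 2 and the highest was 97765013 in the embryo.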
